A study of Homo sapiens with 71 samples.

How the data were processed

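The series measured gene expression in HepG2 cells exposed to surface water. Cells from pooled flasks were spread over dishes, precultured for 72 hours and exposed for 48 hours to medium of which 75% was filtered water from 1 of 16 sites (4 dishes per site; 3 for MIWI) or purified water; the labels call dishes biological replicates. The growth protocol describes 16 control dishes and the series holds 8 control libraries; why the others are absent is not given in the sources used here. RNA was assayed with TempO-Seq, a targeted assay with 1 or more probe pairs per gene. The processing notes name Salmon and the genome build GRCh38. The Salmon version, the probe positions, the gene summary and the normalization step are not given in the sources used here.

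The authors deposited a table of expected counts (estimated read counts) under a name that calls them normalized. The values were checked for their unit. Within each library 1 read was worth between 0.993 and 1.00, and a median of 93.2% (lowest 91.1%) of values under 20 lay within 0.02 of a whole multiple of it, so the values were used as estimated counts, rescaled within each library and not between libraries. The table is held in part: 31012 complete entries in alphabetical order, ending before the entry of RAI14, which is incomplete and was left out; later symbols were not analysed here. The symbols include 14 turned into dates by spreadsheet software and 11631 starting with LOC. Columns were matched to the labels by site; for MIWI and GRMI, where label and column numbers differ, the library numbers are those of the table's columns.

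Values were rounded and fitted with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with TMM scaling, after filterByExpr with a minimum count of 10, which kept 6947 of 12425 features with counts. A single model held a mean for each of the 17 groups of the 71 libraries, with 54 residual degrees of freedom and a common biological coefficient of variation of 0.257. Each site was compared with the controls, the unweighted mean of the 16 sites with the controls, and the 16 sites with one another by an F test. Adjusted p values are Benjamini-Hochberg values over the features of a comparison, and those under 0.05 are called. Errors of log2 changes are standard errors from the test's F value; errors of CPM are SD over libraries. CPM are counts scaled by TMM-adjusted library totals, and M stands for 1e6 counts.

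The 38 gene lists (metal, drug, stress, lipid, hormone, cell cycle, secretion and other-cell markers among them) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and with the correlation estimated from the data; lists with fewer than 4 tested members were not tested. Adjustment was over the 27 lists at the mean of sites and over lists and sites together for the site comparisons. The model, comparisons, lists and named genes were set before the data were examined. Named genes were the largest changes at the mean of sites with the same direction at 14 or more of 16 sites (up to 10 each way), the 3 largest rises and falls per site with every library on 1 side of the control mean, up to 4 members per list that passed in a comparison, the 10 smallest p values between sites, and 13 genes fixed whatever their values. Genes with 0 counts in a group were given a floor of 3 counts over the group; ratios at 1 to 4 counts carry 95% counting intervals. Intervals and floors cover counting error alone, since reads without molecular identifiers are not independent molecules.

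The procedure was tested on simulated data. Of genes changed 2-fold at LRMN the edgeR test recovered 86.6%, of those changed 1.5-fold 37.3% and of those changed 3-fold 98.5%; the mean of sites recovered 83.6%, 98.5% and 100% at 1.5, 2 and 3-fold. The changes were placed in more abundant features alone, so these shares do not cover genes at low CPM. False calls numbered 11 at LRMN and 8 at the mean of sites. With unchanged counts 2 features were called at the mean of sites and 1 over all site comparisons. The simulated libraries held no set of features low together in single libraries, as some real ones did. Alternatives were DESeq2 1.42.0, no filter on low counts, the replicate number as a block, fits with a site and the controls alone, leaving out single libraries or sites, and camera with an estimated correlation. Size factors of the RLE type, leaving out VROH 2, and leaving out VROH 2, CRMI 1 and SRMI 3 together were chosen after seeing the data. Gene positions are from GENCODE release 29 on GRCh38. Site codes are used as given, without a meaning read into them. A gene result that the rule selects is withheld and is not reported here.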

Results

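HepG2 cells, a human hepatoma line that keeps many liver functions, were grown for 48 hours in medium of which 75% was filtered surface water from 1 of 16 Great Lakes tributary sites, or purified water. The 63 site libraries came from 4 dishes per site, except 3 for MIWI, and the 8 control libraries from dishes in purified water, of which the growth protocol describes 16. Sites are named by the 4-letter codes of the labels. TempO-Seq, a targeted assay in which probe pairs that meet on a transcript are ligated and sequenced, gave estimated read counts per gene. The table held here ends at the symbol RAI14 in alphabetical order, so genes with later symbols were not analysed here. Of 12425 features with counts, 6947 were tested.

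Total counts in the part held lay between 8.18 and 14.5 M in the 8 control libraries. They lay between 2.91 and 9.89 M in the site libraries other than VROH 2, which had 8840 counts. Besides VROH 2, the libraries CRMI 1 and SRMI 3 stood apart from the rest of their sites: the SD of log2 differences from the group was 3.06 for VROH 2, 1.90 for CRMI 1 and 1.21 for SRMI 3, over 2829 features. These 3 libraries stayed in the fits that gave the calls, and counts without them stand beside the counts below. In CRMI 1, 388 of the 2829 features were at least 3 log2 units below the other CRMI libraries, and in SRMI 3, 78 were below the rest of their site. They are called probes below, although the entries are per gene.

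**Figure D1:**
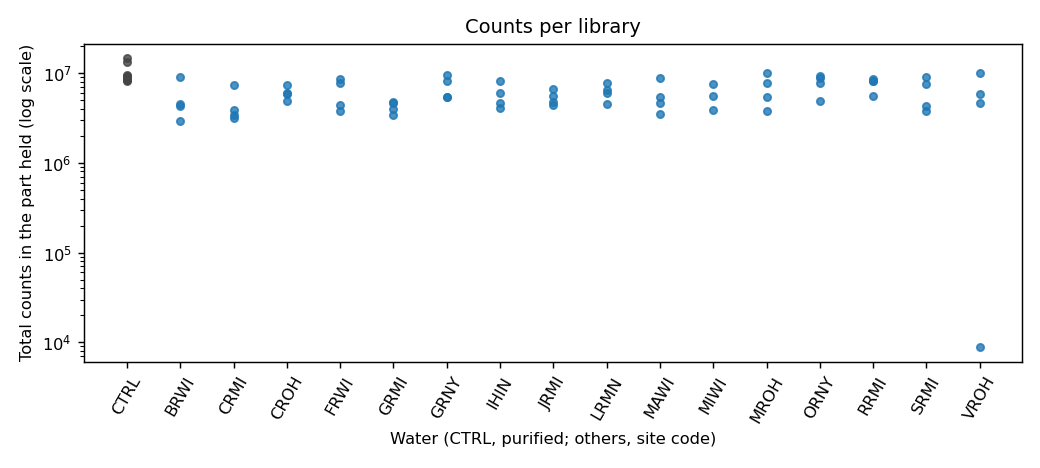
Total counts in the part of the table held (log scale) for each of the 71 libraries, by water; each point is 1 library. The 8 control libraries hold 8.18 to 14.5 M counts, and VROH 2 holds 8840.

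The first comparison asked what the water of these 16 sites had in common against purified water, as the unweighted mean of the 16 sites minus the controls. Its errors and p values come from the spread between dishes within groups. The spread between sites does not enter them, so they hold for these 16 sites and not for surface water at large. Metallothionein genes, whose small cysteine-rich proteins bind zinc, copper and cadmium, rose. MT1M (chromosome 16, 56632233 to 56633986, plus strand) went from 16.5 ± 3.80 CPM (SD, n = 8) in controls to 34.7 as the mean of sites, a log2 change of 0.98 ± 0.12 (SE, adjusted p = 2.05e-07). Its value was above the controls at 16 of 16 sites, and 10 sites passed the test alone. MT1G (chromosome 16, 56666731 to 56668065, minus strand) went from 233 ± 37.6 to 434 CPM, a log2 change of 0.81 ± 0.12 (adjusted p = 2.19e-05), with 15 of 16 sites above the controls. MT2A (chromosome 16, 56608199 to 56609497, plus strand) rose by 0.77 ± 0.17 (adjusted p = 0.0388), from 8.93 ± 1.65 to 15.9 CPM, at 16 of 16 sites. NRN1 (chromosome 6, 5997999 to 6007605, minus strand), which encodes neuritin, a protein anchored to the cell surface, rose by 0.50 ± 0.11 (adjusted p = 0.0388), from 5.75 ± 1.34 to 8.55 CPM, at 15 of 16 sites. MT1X reached a larger value, 1.16 ± 0.29, from 0.372 CPM in controls, and did not pass (adjusted p = 0.215).

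edgeR called 4 features, 4 higher and 0 lower. At an unadjusted p under 0.05 there were 162, fewer than the 347 that chance alone would give. DESeq2 called 6. Without the 3 libraries 12 were called, the 4 among them, and 336 of 6916 features had an unadjusted p under 0.05. MT2A lost its call when any 1 control was left out, with log2 values of 0.71 to 0.80 and an adjusted p of up to 0.237 (without CTRL 3). NRN1 lost its call without any 1 of CTRL 2 to CTRL 8, with an adjusted p of up to 0.275 (without CTRL 4), so that 2 genes were called without CTRL 2, 3, 4, 5, 6, 7 or 8. Without VROH 2 alone 7 were called. Sites share the 8 controls, so equal directions across sites are common by construction: 4.61% of features had at least 14 of 16 sites on 1 side, against 18.7% in simulated unchanged groups. Against the odd-numbered and the even-numbered controls taken apart, and without the 3 libraries, MT1M, MT1G and MT2A were above each set at 16 of 16 sites, and NRN1 at 15 and 16. The 4 genes were selected against these same 8 controls, so this is no independent check.

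**Figure D2:**
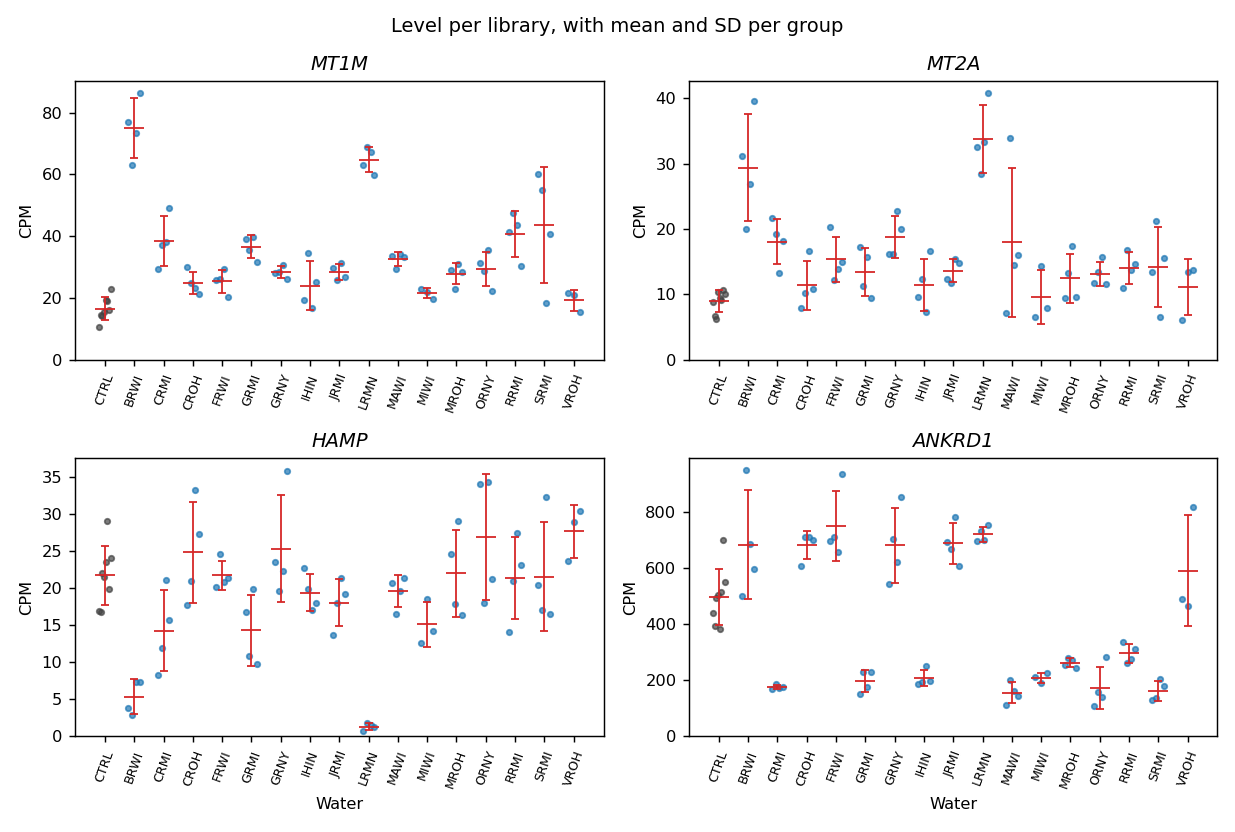
CPM of MT1M, MT2A, HAMP and ANKRD1 in each library by water, with VROH 2 left out; red marks give the group mean and SD. HAMP averages 1.32 CPM at LRMN against 21.8 in controls, and MT1M averages 75.0 CPM at BRWI against 16.5.

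Among the fixed gene lists at the mean of sites, metallothioneins and metal response rose (median log2 change 0.77, 7 members tested, adjusted p = 1.44e-31, and 5.52e-14 with an estimated correlation). Of its members 3 rose, MT1M, MT1G and MT2A; adjusted over the list alone, 5 rose and 1 fell. PXR and CAR targets, genes of drug and steroid handling, rose by the preset test (median 0.03, 0 of 7 members past the threshold, 1 higher adjusted over the list alone, adjusted p = 0.0499), with adjusted p = 0.269 with an estimated correlation. Acute phase proteins, which liver cells secrete in inflammation, fell by the preset test (median -0.08, 0 of 12 members past the threshold, 1 lower adjusted over the list alone, adjusted p = 0.0262), with adjusted p = 0.537 with an estimated correlation. Without the 3 libraries PXR and CAR targets and metallothioneins were called and acute phase proteins were not. The number of lists called went from 3 to 1 without CTRL 3, CTRL 6 or CTRL 7.

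The remaining 24 tested lists did not pass at the mean of sites, by edgeR counts and limma camera. ATF4 integrated stress response had 11 members tested, a median of -0.12 and an adjusted p of 0.0902; ASNS and PSAT1, 2 of its members, were among the 388 probes low in CRMI 1. p53 and DNA damage response had a median of -0.07 and mitosis and cell cycle -0.07, both with an adjusted p of 0.0902. Iron handling had a median of -0.06 (adjusted p = 0.145; 1 lower adjusted over the list alone) and oestrogen and androgen response -0.07 (adjusted p = 0.445). The adjusted p was 0.644 for fetal liver and liver cancer markers (median 0.02). It was 0.800 for heat shock response (0.04), ER unfolded protein response (0.00), hepatocyte secreted proteins and identity (0.01), immediate early genes, amino acid and urea metabolism and oxidative phosphorylation (-0.03). It was 0.842 for DNA replication (-0.06), glycolysis (-0.03) and inflammatory NF-kB targets (-0.01). It was at least 0.942 for NRF2 antioxidant response, cholesterol biosynthesis, fatty acid synthesis, PPARA targets and fatty acid oxidation, glucocorticoid targets and gluconeogenesis, hypoxia response, interferon response, autophagy and lysosome, and replication-dependent histones, whose medians lay between -0.09 and -0.02. Median and test direction differed in sign for NRF2 antioxidant response, fatty acid synthesis, inflammatory NF-kB targets, immediate early genes, amino acid and urea metabolism, autophagy and lysosome, and ER unfolded protein response. The mean differed from the test direction for NRF2 antioxidant response and fatty acid synthesis. In all 24 lists 0 members passed at the mean of sites, and 0 also adjusted over the list alone except in iron handling.

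Too few members were tested (under 4) for 11 lists: AHR targets (3), bile acid metabolism (3), retinoic acid targets (3), osmotic stress (3), thyroid hormone targets (1), cytosolic ribosomal proteins (0), mitochondrially encoded transcripts (0), and the markers of immune (3), fibroblast and stellate (2), endothelial (2) and squamous or other epithelial cells (1).

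Of the genes fixed for checking, MT2A passed at the mean of sites and the others tested did not. CYP1A1, the dioxin-responsive P450 and an AHR target, was at 78.8 ± 14.6 CPM in controls and 97.1 at the sites, a log2 value of 0.27 ± 0.29 (adjusted p = 1.00); it was among the probes low in CRMI 1. The haem oxygenase HMOX1 was at -0.02 ± 0.08, the stress factor DDIT3 at -0.14 ± 0.08, the cell cycle inhibitor CDKN1A at -0.27 ± 0.23 and albumin (ALB) at 0.13 ± 0.22. The mitochondrial fatty acid importer CPT1A was at -0.20 ± 0.14, the lipid droplet protein PLIN2 at 0.08 ± 0.13 and the proliferation marker MKI67 at 0.02 ± 0.11. CYP1A2 (1 count over all libraries), CYP3A4 (41) and HMGCS1 (102) had too few counts to test.

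Whether sites differed from one another was tested by an F test on the 16 site means, without the controls. Its p values also come from the spread between dishes within groups. ANKRD1 (chromosome 10, 90912096 to 90921276, minus strand) and CCN2 (chromosome 6, 131948176 to 131951373, minus strand), targets of the Hippo pathway effector YAP, lay on both sides of the controls; for ANKRD1 0 values above them passed and 6 below them did. ANKRD1 averaged 498 ± 101 CPM (SD, n = 8) in controls, 156 ± 37.8 at MAWI (n = 4) and 751 ± 125 at FRWI (n = 4), with F = 22.2 and adjusted p = 1.97e-15. CCN2 had F = 18.7 (adjusted p = 5.42e-14), with log2 changes from -1.29 at CRMI to 1.24 at LRMN. GPD1, the cytosolic glycerol-3-phosphate dehydrogenase (chromosome 12, 50103819 to 50111319, plus strand), had F = 22.0 and ran from -1.45 at LRMN to 0.95 at CRMI. HAMP, which encodes the iron hormone hepcidin (chromosome 19, 35280716 to 35285143, plus strand), had F = 17.6 (adjusted p = 1.44e-13).

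PLPPR1, a membrane protein related to lipid phosphatases (chromosome 9, 101028709 to 101325135, plus strand), had F = 22.1 and ran from -0.84 at SRMI to 0.81 at LRMN. MOSPD1, the tRNA methyltransferase ALKBH8 (F = 17.6), the apoptosis initiator CASP8 (17.3) and the matrix protein NPNT (17.2) completed the smallest p values with CALM3 (17.8), which rested on VROH 2: without it the F value was 0.856 (adjusted p = 0.731). In the metallothionein genes F was 13.9 for MT1M, 13.0 for MT1G and 5.94 for MT2A, and for NRN1 6.75. The F test called 2073 of 6947 features, 2463 with DESeq2, and 3446 of 6916 without the 3 libraries, 2025 of them shared with the 2073.

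**Figure D3:**
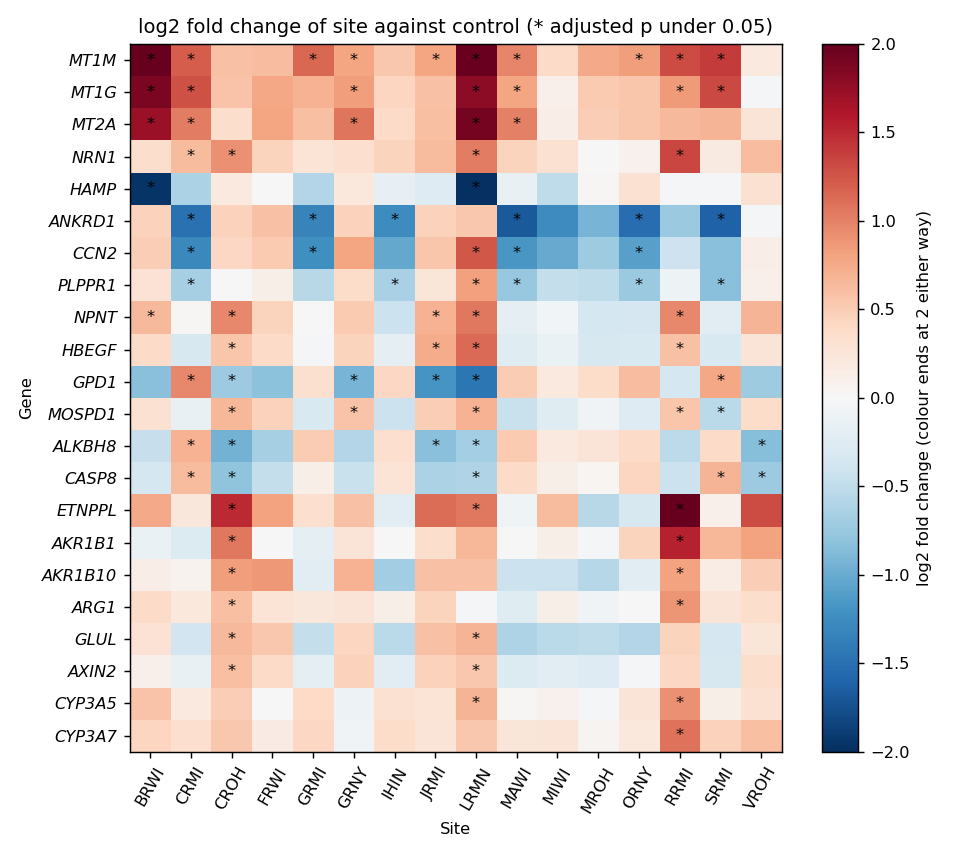
Log2 change against the controls of named genes (vertical) at each of the 16 sites (horizontal), by edgeR with all libraries; a star marks an adjusted p under 0.05. HAMP is lowest at LRMN (-4.05), and ANKRD1 is starred at 6 of the 10 sites where it is lower than the controls.

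Each site was then compared with the controls. Here too errors and p values come from the spread between dishes within groups, so they do not cover other water of the same site. LRMN gave 348 called genes, the most of any site, 153 higher and 195 lower. Without the 3 libraries 646 were higher and 567 lower. The hepcidin gene HAMP fell from 21.8 ± 4.01 CPM (n = 8) to 1.32 ± 0.494 (n = 4), a log2 change of -4.05 ± 0.32 (adjusted p = 9.75e-15). MT1F rose by 2.27 ± 0.39 (adjusted p = 0.00011), MT1M by 1.97 ± 0.17, MT2A by 1.92 ± 0.24 and MT1G by 1.79 ± 0.17. PSAT1, an enzyme of serine synthesis, fell by 1.23 on the log2 scale (68.2 to 29.2 CPM, adjusted p = 0.0044); the replication licensing factor CDC6 fell by 1.01 and the replication factor GINS2 by 0.85, and the chemokine CXCL2 by 0.88. AXIN2, a WNT target, rose by 0.54 ± 0.13. These calls held when any 1 library was left out.

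Asparagine synthetase ASNS fell by 2.00 on the log2 scale, the respiratory chain carrier CYCS by 1.09, the replicative helicase subunit MCM3 by 0.66, the stress hormone target FKBP5 by 0.59 and the bile acid receptor NR1H4 by 0.52. Lysozyme LYZ rose by 1.01, the hypoxia gene CA9 by 0.76, glutamine synthetase GLUL and CYP3A5 each by 0.68 and the glycolytic enzyme PGAM1 by 0.67; the metallothionein MT1X rose by 1.88. The endothelial marker CDH5 fell by 2.01, from 1.17 to 0.289 CPM. All of these passed without the 3 libraries. With 1 LRMN library fewer, values moved little while adjusted p rose. Without LRMN 2 all but CYP3A5 were short of the threshold, with an adjusted p from 0.0582 for MT1X (1.66) to 0.218 for CA9 (0.58); ASNS was at -2.06, CYCS at -0.96, MCM3 at -0.64, FKBP5 at -0.49, NR1H4 at -0.48, LYZ at 0.97, GLUL at 0.64, PGAM1 at 0.56 and CDH5 at -1.88. Without LRMN 4 adjusted p was 0.108 for ASNS and CYP3A5, 0.0619 for CA9 and CYCS, 0.052 for MCM3, 0.0662 for LYZ and 0.113 for CDH5. Without LRMN 1 it was 0.0669 for CYCS, 0.05 for CYP3A5 and 0.0509 for CDH5, and without LRMN 3 it was 0.0959 for CYP3A5. ABRACL had 0 counts at LRMN against 87 in the controls, at least 8.14-fold lower at a floor of 3 counts over the group, while the 95% counting interval of the ratio, from 0 to 0.154, is wider than that floor; its adjusted p of 0.0379 rose to as much as 0.117 without single libraries. CHRFAM7A had 2 counts, a ratio of 0.111 (95% counting interval 0.0132 to 0.419; adjusted p = 0.0195), and lost its call without LRMN 3 (0.0619) or LRMN 4 (0.101). DDIT3 (-0.46), CDT1 (-0.45), CEBPA (-0.61) and IREB2 (0.75) lost theirs without any of 6 to 10 of 12 libraries, with an adjusted p of up to 0.277. The number of genes was 127 without LRMN 2, 217 without LRMN 3, 204 without LRMN 4, 600 without VROH 2 and 1213 without the 3 libraries, which kept 347 of the 348.

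BRWI gave 10 called genes, 7 higher and 3 lower. MT1M rose by 2.19 ± 0.17 to 75.0 ± 9.72 CPM (n = 4, adjusted p = 1.24e-14), MT1G by 1.88 ± 0.17 to 857 CPM and MT2A by 1.73 ± 0.25 to 29.4 CPM. HAMP fell to 5.34 ± 2.36 CPM, a log2 change of -1.96 ± 0.26 (adjusted p = 9.55e-07). These 4 calls held without any 1 library. INHBB, a subunit of activin B, fell by 1.11 (adjusted p = 0.00699), which was 0.069 without BRWI 1, 0.056 without BRWI 3 and 0.113 without BRWI 4. CDA, cytidine deaminase, fell by 0.64 (adjusted p = 0.0464) and MT1X rose by 1.86 (adjusted p = 0.049); they lost their calls without 11 and 10 of 12 single libraries, with an adjusted p of up to 0.267 and 0.733, and without BRWI 4 the MT1X value was 0.89. The number of genes was 4 to 6 without any 1 BRWI library or CTRL 4, 5, 6 or 8, 33 without VROH 2 and 79 without the 3 libraries; DESeq2 called 22.

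CRMI gave 260 called genes, 140 higher and 120 lower. Without the 3 libraries 205 were higher and 349 lower. MT1X rose by 2.15 ± 0.43 (0.372 to 1.66 CPM, adjusted p = 0.00258), MT1G by 1.27 ± 0.18 and MT1M by 1.21 ± 0.18. The acute phase protein ITIH3 fell by 1.43 (17.7 to 6.67 CPM, adjusted p = 0.00717) and the NRF2 target OSGIN1 fell by 1.30 (12.1 to 4.70 CPM, adjusted p = 0.0107). These calls held without any 1 library, with the 388 low probes of CRMI 1 in the group. Without CRMI 1, adjusted p rose to 0.0731 for ANXA1 (1.39, then 1.25), 0.0645 for MT2A (1.02, then 0.93) and 0.0901 for JUNB (-1.12, then -0.74). It rose to 0.0758 for FADS1 (-0.98, then -0.64), 0.0661 for COX4I1 (-1.04, then -0.93) and 0.0822 for LYZ (-1.08, then -0.95). For BIRC3 it was 0.12 (-1.11, then -0.69), for CXCL8 0.233 (0.65, then 0.35) and for DNAJC3 0.121 (0.48, then 0.31). For MCM3 it was 0.179 (0.59, then 0.43), for MT1E 0.262 (-0.90, then -0.48) and for DUOXA2 0.113. In the fit without the 3 libraries ANXA1, MT2A, JUNB, FADS1, COX4I1, LYZ, DNAJC3 and MCM3 passed, with an adjusted p of up to 0.0465. There BIRC3 (0.0620), CXCL8 (0.156), MT1E (0.152) and DUOXA2 (0.0673) did not pass. DUOXA2 had 2 counts at CRMI, a ratio of 0.0935 (95% counting interval 0.0112 to 0.347), and EBLN2 had 4 counts, all in CRMI 1, a ratio of 0.197 (0.0526 to 0.522); without CRMI 1 EBLN2 had 0 counts at the site. KLRK1 fell by 2.08 with all libraries and was at -1.56 without the 3 (adjusted p = 0.132). EBLN2, KLRK1, MT1E and MCM3 were also lost without 5 to 8 of 12 single libraries. Counts were 148 without CRMI 1, 508 without VROH 2 and 554 without the 3 libraries, which kept 148 of the 260; CRMI 4 alone also ended LYZ (0.0583).

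CROH gave 149 called genes, 58 higher and 91 lower, and RRMI 59, 36 higher and 23 lower. ETNPPL (chromosome 4, 108742040 to 108763054, minus strand), an enzyme that breaks down phosphoethanolamine, rose at RRMI from 1.62 ± 0.324 CPM (n = 8) to 7.86 ± 2.45 (n = 4), a log2 change of 2.25 ± 0.27 (adjusted p = 5.59e-08), and at CROH by 1.5 ± 0.29 (adjusted p = 0.0023). The urea cycle enzyme ARG1 rose by 0.89 ± 0.14 at RRMI (50.7 to 93.9 CPM, adjusted p = 1.44e-05) and by 0.60 at CROH, where adjusted p was 0.0535 without CROH 1. Aldose reductase AKR1B1 (chromosome 7, 134442350 to 134459284, minus strand), an osmotic stress gene, rose by 1.54 ± 0.28 at RRMI (adjusted p = 0.000371). The fetal liver P450 CYP3A7 (chromosome 7, 99684957 to 99735196, minus strand) rose by 1.09 ± 0.17 at RRMI (18.7 to 39.9 CPM, adjusted p = 1.61e-05). At RRMI MT1M rose by 1.31 ± 0.17 and MT1G by 0.85 ± 0.18.

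Further RRMI calls were lost without single libraries: C7 (1.37) and C11orf65 (-1.15) without RRMI 2 (adjusted p = 0.084 and 0.0859), CYP3A5 (0.92) without RRMI 1 (0.0707), C11orf65 without RRMI 1 (0.0563), ECSCR (-1.44) without RRMI 2 (0.106) or RRMI 4 (0.0708), LYRM9 (-1.14) without RRMI 3 (0.181), RRMI 2 (0.059) or RRMI 4 (0.0792), and AKR1B10 (0.81) without any of 5 libraries (up to 0.139). At CROH, AXIN2 (0.60), AKR1B10 (0.84) and PFKFB3 (0.84) lost their calls without CROH 3 (0.0601, 0.226 and 0.238), and APCDD1 (1.31), a WNT inhibitor, without CROH 1 (0.064) or CROH 4 (0.112). ERMARD had 3 counts at CROH, a ratio of 0.159 (95% counting interval 0.0320 to 0.486), and lost its call without CROH 2, 3 or 4 (up to 0.173). AKR1B1 (1.05), IRF2BP1 (1.42), ARMH1 (-2.13), JRKL (-2.01), GLUL (0.64), HK1 (0.77) and OSGIN1 (0.91) lost theirs without 6 to 10 of 12 libraries. The CROH count was 98, 44, 46 and 42 without CROH 1, 2, 3 and 4, 99 without CTRL 2, 95 without CTRL 5, 289 without VROH 2 and 709 without the 3 libraries. The RRMI count was 38 without RRMI 2, 34 without RRMI 4, 121 without VROH 2 and 198 without the 3; all of the 149 and the 59 were among the genes called without the 3.

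ANKRD1 fell at 6 sites. The log2 changes were -1.68 ± 0.26 at MAWI (adjusted p = 0.000108), -1.61 ± 0.26 at SRMI (8.67e-05), -1.53 ± 0.25 at ORNY (0.000796), -1.50 at CRMI (0.000262), -1.34 ± 0.25 at GRMI (0.00579, 498 to 197 CPM) and -1.26 ± 0.25 at IHIN (0.0316). CCN2 fell by 1.29 at CRMI, by 1.23 at GRMI, by 1.17 at MAWI and by 1.09 at ORNY (adjusted p = 0.0476) and rose by 1.24 at LRMN (adjusted p = 0.00049), and the kinase gene PIM1 fell by 1.38 at MAWI and by 1.20 at ORNY. At MAWI the growth factor AREG rose by 1.09 ± 0.24 (8.86 to 18.9 CPM, adjusted p = 0.0163), FAM111B by 1.09, MT1M by 0.98, MT2A by 1.01 and MT1G by 0.78. At SRMI MT1M rose by 1.40 ± 0.18 and MT1G by 1.32 ± 0.18. The ANKRD1 calls at MAWI and SRMI and the MT1M calls at MAWI, SRMI and GRMI (1.15 ± 0.18, adjusted p = 0.000163) held without any 1 library.

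ANKRD1 lost its call at ORNY without ORNY 1 (adjusted p = 0.053), at GRMI without GRMI 1 (0.147) or GRMI 3 (0.0771), and at IHIN without any IHIN library, CTRL 3, CTRL 4 or CTRL 7 (up to 0.248). CCN2 at MAWI lost its call without MAWI 1 (0.144) or MAWI 3 (0.0622), PIM1 at MAWI without MAWI 1 (0.134) or MAWI 3 (0.0622), AREG without MAWI 1 (0.0673), MAWI 2 (0.0569) or MAWI 3 (0.0643), and MT1G at MAWI without CTRL 2 (0.0501), MAWI 1 (0.0519), MAWI 2 (0.0737) or MAWI 3 (0.0568). MT2A at MAWI lost its call without 8 of 12 libraries (0.52, adjusted p = 0.446, without MAWI 2) and FAM111B without 7 (0.76, adjusted p = 0.514, without MAWI 1). At ORNY MT1M (0.84) and F13B (-1.14) were lost without ORNY 1, 2 or 3, with an adjusted p of up to 0.445, and AP1S3 (0.85) without ORNY 1 or ORNY 3 (up to 0.445). NDOR1 (0.82) and PIM1 at ORNY were lost without 9 and 8 of 12 libraries, ORNY 1, 2 and 3 among them, with an adjusted p of up to 0.479 and 0.489. PLPPR1 at IHIN (-0.65) and CCN2 at GRMI were lost without 10 and 5 of 12 libraries. The calls of ANKRD1 at CRMI and of CCN2 at CRMI, ORNY and LRMN were not rerun without single libraries.

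At SRMI, ITPRIPL1 (1.66) and BTBD19 (1.34) were called through SRMI 3: without it their log2 values were 0.11 and 0.65 (adjusted p = 0.971 and 0.288). Without SRMI 3 the gluconeogenic enzyme PCK2 went from 1.47 to -0.11 (adjusted p = 0.985), ATF5 from 0.96 to 0.45, CEBPA from 0.70 to 0.46 and IFI6 from 0.64 to 0.15, all short of the threshold. IGFBP3 (-1.22) was at -0.97 without it (adjusted p = 0.0586), LEPR (-1.07) at -1.06 (0.0702) and the hypoxia gene ANKRD37 (-1.05) at -0.74 (0.359). In the fit without the 3 libraries IGFBP3 (-0.96, adjusted p = 0.000192), LEPR (-1.05, 0.0191) and ANKRD37 (-0.74, 0.0322) passed. ITPRIPL1, BTBD19, PCK2, ATF5, CEBPA and IFI6 did not pass there. SRMI gave 79 called genes, 57 higher and 22 lower; the count was 5 without SRMI 3, 119, 216 and 200 without SRMI 1, 2 and 4, 52 without CTRL 2, 51 without CTRL 4 and 220 without VROH 2. Without the 3 libraries it was 88 (29 higher, 59 lower), 28 of them shared.

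MAWI gave 25 called genes (14 higher, 11 lower), ORNY 14 (4 higher, 10 lower), GRMI 3 (1 higher, 2 lower) and IHIN 2 (0 higher, 2 lower). Without the 3 libraries the counts were 326 (149 higher, 177 lower), 283 (100 and 183), 38 (10 and 28) and 38 (9 and 29). Without VROH 2 alone they were 108, 110, 8 and 7. The MAWI count was 7 without MAWI 1, 14 without MAWI 3 and 56 without CTRL 5. At ORNY it was 0, 2, 1 and 89 without ORNY 1, 2, 3 and 4, 9 without CTRL 1, 8 without CTRL 3 and 9 without CTRL 7. The GRMI count was 1 without GRMI 1 or GRMI 3. At IHIN it was 0 without any 1 IHIN library, CTRL 3, CTRL 4 or CTRL 7, and 1 without CTRL 1, 2 or 6.

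GRNY gave 10 called genes (5 higher, 5 lower), JRMI 9 (3 higher, 6 lower) and FRWI 5 (0 higher, 5 lower). At JRMI the growth factor HBEGF rose by 0.75 ± 0.15 (35.9 to 60.2 CPM, adjusted p = 0.0134), NPNT by 0.69 and MT1M by 0.78, and GPD1 fell by 1.19 (to 5.28 CPM, adjusted p = 0.00439), CFAP70 by 1.93 and ANKRD65 by 0.99. At GRNY MT2A rose by 1.07, ANXA13 by 0.84, MT1G by 0.83 and MT1M by 0.78, and GBP1 fell by 1.06 (adjusted p = 0.0185), GPD1 by 0.93 and PYCR3, an enzyme of proline synthesis, by 0.79. At FRWI KRCC1 fell by 1.84, CFAP70 by 1.75 and the amylase gene AMY2A by 1.13 (adjusted p = 0.0354). Every one of these calls was lost without at least 1 library, GPD1 at JRMI without JRMI 2 (0.0581), HBEGF without JRMI 1 (0.0632), JRMI 2 (0.0832) or JRMI 3 (0.074), NPNT without JRMI 2 (0.209) or JRMI 4 (0.0952), GBP1 without CTRL 5 (0.0536), GRNY 1 (0.0533), GRNY 2 (0.0821) or GRNY 4 (0.144), CFAP70 at JRMI without any JRMI library (0.0581 to 0.161), and the rest without 6 to 11 of 12 libraries. Every one passed in the fit without the 3 libraries. There GRNY gave 634 genes (301 higher, 333 lower), JRMI 201 (123 and 78) and FRWI 151 (74 and 77).

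Counts at these sites moved with single libraries. Without VROH 2 GRNY gave 37, JRMI 76 and FRWI 23. GRNY gave 0 without CTRL 5, GRNY 2 or GRNY 4, 1 without CTRL 3 or GRNY 3, 3 without CTRL 6 or GRNY 1, 4 without CTRL 2 or CTRL 4, and 6 without CTRL 8. JRMI gave 19 without CTRL 7, 3 without JRMI 1, 0 without JRMI 2, and 5 without JRMI 3 or JRMI 4. FRWI gave 1 without CTRL 2, 5 or 8, FRWI 2 or FRWI 4, 2 without CTRL 1 or CTRL 7, and 3 without FRWI 3.

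VROH gave 9 called genes, 7 higher and 2 lower, with VROH 2 in the group. ALKBH8 fell by 0.84 ± 0.19 (adjusted p = 0.0391) and CASP8 by 0.72 ± 0.17 (adjusted p = 0.0433), and both passed without the 3 libraries (-0.84 and -0.76). PALM3 went from 3.08 to 0.29 without VROH 2 (adjusted p = 0.809). The count was 0 without VROH 2 (edgeR) and 24 without VROH 3. Without the 3 libraries it was 9 (4 higher, 5 lower), 2 of them shared. ALKBH8 and CASP8 also lost their calls without 6 and 9 of 11 other single libraries. At MIWI edgeR called 0 genes, with 211 at an unadjusted p under 0.05, and DESeq2 called 2. At MROH edgeR called 0 genes, with 267 at an unadjusted p under 0.05, and DESeq2 called 2. Chance alone would give 347 at an unadjusted p under 0.05 at each site. Without VROH 2 MIWI and MROH each gave 1, and without the 3 libraries MIWI gave 1 and MROH 6. In the fit without the 3, 556 of 6916 features at MIWI and 606 at MROH had an unadjusted p under 0.05.

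**Figure D4:**
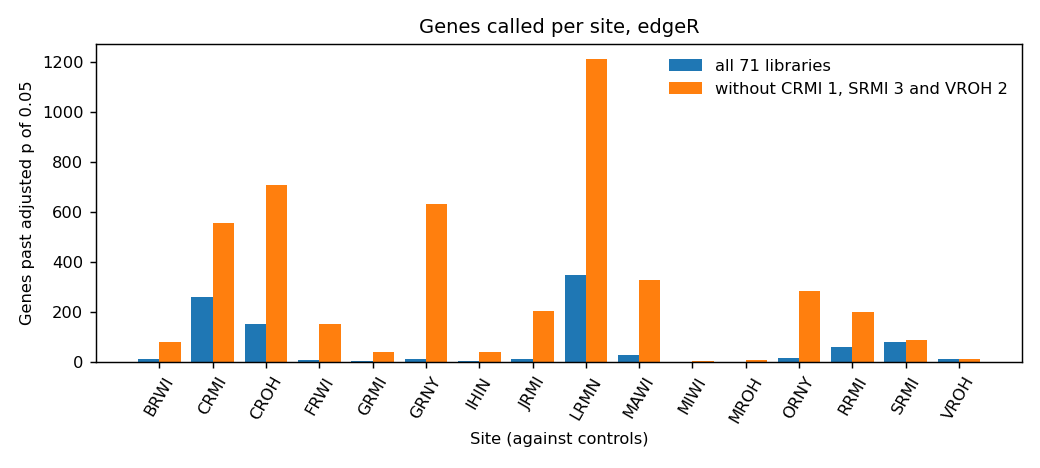
Number of genes past an adjusted p of 0.05 (vertical, edgeR) at each site against the controls, with all 71 libraries (blue) and without CRMI 1, SRMI 3 and VROH 2 (orange). LRMN goes from 348 to 1213 and GRNY from 10 to 634.

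Over the 27 lists and 16 sites, 32 pairs of list and site passed. Metallothioneins and metal response rose at 13 sites, all but CROH, MIWI and VROH, with a median log2 change from 0.38 at IHIN to 1.88 at LRMN. With an estimated correlation the call was lost at IHIN (adjusted p = 0.269 with an estimated correlation) and ORNY (0.0685). The smallest adjusted p was 2.82e-34 at BRWI (median 1.73), where 4 of 7 members rose, 5 adjusted over the list alone. At LRMN 5 rose, 5 adjusted over the list alone. At CRMI 4 rose and 1, MT1E, fell; adjusted over the list alone the numbers were the same. Members that rose numbered 3 at GRNY and MAWI, 2 at RRMI and SRMI, 1 at GRMI, JRMI and ORNY, and 0 at FRWI, IHIN and MROH. Adjusted over the list alone they numbered 4 at GRMI, GRNY, JRMI, MAWI, ORNY, RRMI and SRMI, 3 at FRWI and MROH, and 1 at IHIN, with 1 lower at ORNY and RRMI.

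The other 19 pairs were lost with an estimated correlation. PXR and CAR targets rose at RRMI, where CYP3A5 and CYP3A7 rose (2 of 7 members, 2 adjusted over the list alone; median 0.08, adjusted p = 0.00665, and adjusted p = 0.0791 with an estimated correlation). ATF4 integrated stress response fell at LRMN (median -0.46), where ASNS, PSAT1 and DDIT3 fell (3 of 11 members, 4 adjusted over the list alone), with adjusted p = 0.629 with an estimated correlation, and at BRWI (median -0.32, 0 members, 0 adjusted over the list alone; 0.477). The probes of ASNS and PSAT1 were in the CRMI 1 set, which was also low in LRMN 4 (mean log2 value -1.13). DNA replication fell at LRMN (median -0.45, 4 members, 5 adjusted over the list alone), with adjusted p = 0.477 with an estimated correlation. It rose at MAWI (median 0.33, 0 members, 1 adjusted over the list alone; 0.700) and ORNY (median 0.33, 0 members, 0 adjusted over the list alone; 0.749).

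Mitosis and cell cycle fell at GRMI (median -0.28, 0 members, 3 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation), IHIN (median -0.24; 0.629) and MROH (median -0.22; 0.495), the last 2 with 0 members and 0 adjusted over the list alone. Iron handling fell at GRMI (median -0.28; adjusted p = 0.399 with an estimated correlation), IHIN (-0.30; 0.585) and MIWI (-0.28; 0.370), with 0 members and 0 adjusted over the list alone. Acute phase proteins fell at GRMI (median -0.23; adjusted p = 0.700 with an estimated correlation) and VROH (-0.23; 0.598), with 0 members and 0 adjusted over the list alone; the VROH call was lost without the 3 libraries (adjusted p = 0.802). NRF2 antioxidant response rose at GRNY (median 0.28, 0 members, 2 adjusted over the list alone; adjusted p = 0.580 with an estimated correlation) and fell at IHIN (median -0.14, 0 members, 3 adjusted over the list alone; 0.495). p53 and DNA damage response fell at MIWI (median -0.18, 0 members, 1 adjusted over the list alone; adjusted p = 0.226 with an estimated correlation). PPARA targets and fatty acid oxidation fell at ORNY (median -0.19, 0 members, 3 adjusted over the list alone; 0.615), and glycolysis fell at SRMI (median -0.30, 0 members, 0 adjusted over the list alone; 0.717).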

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

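The tests of shared paralog reads, of single libraries, of separately handled dishes, of sampling depth in CRMI 1 and of a fixed probe set were chosen only after the results were seen.

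Metallothionein genes were higher at the mean of sites and differed between sites: the F value of MT1M was 13.921, of MT1G 13.006 and of MT2A 5.938. The depth gap between control and site libraries would move the summed metallothionein level by -0.0669 on the log2 scale. The observed change was 0.78 ± 0.0725, which argues against depth. A shift of reads between paralogs would leave the sum unchanged, and the sum rose by 0.78. MT1G makes up most of the sum (178194 counts over all libraries, against 14135 for MT1M and 6766 for MT2A). The sum therefore mostly follows MT1G and cannot tell whether the smaller members took up its reads. MT1M was at 1.01 without the 3 libraries that stand apart. The sum exceeded the highest control at 14 of 16 site means. Metals in the water may explain it. The labels give no metal levels, so this stays open and untested. Control dishes handled as a set of their own cannot be told apart from the water in the mean of sites, because the labels give no batch. The count of 4 genes at the mean of sites was reached in 6 of 100 splits of the libraries, the highest other split giving 423, so chance is not excluded for the count; a split with so many genes points to a structure of the samples, and which one was not tested.

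ANKRD1 (F = 22.19) and CCN2 (F = 18.699) lay on both sides of the controls by site, ANKRD1 mostly below: without the 3 libraries 9 site means were below the lowest control library and 2 above the highest, and 0 rises passed with all libraries. The largest depth gap between groups would move ANKRD1 by 0.33 on the log2 scale against a range of 2.33 over site means, and at 15 of 16 sites all libraries, without the 3, lay on 1 side of the control mean; both argue against depth and single libraries. Dishes handled in separate batches cannot be told apart from sites, because the labels give no batch; the range over control libraries was 37.5% of that over site means. CCN2 had the sign of ANKRD1 at 16 of 16 sites without the 3 libraries. An effect of the water on cell attachment or density is a candidate explanation that was not tested.

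In CRMI 1, 388 of 2829 features were at least 3 log2 units below the rest of the site, and 78 in SRMI 3, with 18 in both. The CRMI 1 set was chosen as abundant features at least 3 log2 units low in that library. Its median of 29 counts where 768 were expected follows from that choice and does not test sampling at low depth. CRMI 1 was the deepest library of its site, at 7.30 M counts against 3.18 to 3.84 M, which argues against low depth there. RNA of other cells in place of HepG2 is argued against by hepatocyte genes, whose median was 0.65 above the rest of the site. The CRMI 1 set lay below all 1000 random sets in 15 of 68 other libraries. Its scores there ran from -1.71 in GRNY 2 and -1.56 in JRMI 2 to -0.07 in JRMI 3. An assay step that fails for a fixed set of probes would give this, and so would any genes that vary together. The comparison with random sets therefore cannot tell these apart. No biological explanation was tested.

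Samples far from the rest of their group were found in 15 of 148 groups, where chance gives about 1 in 20. Total counts were 7.3 M in CRMI 1 and 5.555 M in RRMI 4. The TMM factor was 1.098 in CTRL 5 and 7.897 in VROH 2, and 9200 and 1879 features were detected there. In GRMI 4 the 10 most abundant features took 29.15% of counts. DUOXA2 was at 0.6303 CPM in CRMI 2, EBLN2 at 0.5366 in CRMI 1, ERMARD at 0 in CROH 3 and CCN2 at 126.6 in GRMI 2. The first 3 rest on few counts over the whole site, 2 for DUOXA2, 4 for EBLN2 and 3 for ERMARD. The GRMI libraries of CCN2 lay close together, from -1.32 to -1.14 log2 units against the control mean. ITPRIPL1 was at 122.7 CPM and BTBD19 at 36.9 in SRMI 3, PALM3 at 1545 in VROH 2 and NRN1 at 8.568 in CTRL 1.

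The difference between sites was also tested for NRN1 (F = 6.746), PLPPR1 (22.054), GPD1 (21.951), MOSPD1 (18.977), CALM3 (17.838, from VROH 2), HAMP (17.627), ALKBH8 (17.572), CASP8 (17.257) and NPNT (17.185).

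Each count of called genes was compared with 21 splits per site, the real one included. At 12 sites 1 split, the real one, was as large, which is under 0.05 and the smallest share 21 splits can give, not adjusted for 16 sites, so chance is excluded only at that level: the real counts and highest others were 10 and 1 at BRWI, 260 and 0 at CRMI, 149 and 0 at CROH, 5 and 0 at FRWI, 3 and 0 at GRMI, 10 and 1 at GRNY, 2 and 0 at IHIN, 9 and 1 at JRMI, 348 and 5 at LRMN, 25 and 0 at MAWI, 14 and 1 at ORNY, and 59 and 1 at RRMI. The counts at GRNY, IHIN, JRMI and ORNY fall to 0 without some single libraries, and those at IHIN, GRMI and FRWI are 5 or less, so little rests on them. The runs that gave 0 kept VROH 2, CRMI 1 and SRMI 3. Without these 3 libraries GRNY gave 634, IHIN 38, JRMI 201, ORNY 283, GRMI 38 and FRWI 151, with every original call among them. That fit kept GRNY 2, GRNY 3, GRNY 4, JRMI 2 and FRWI 1, which were low in the CRMI 1 or SRMI 3 set. Libraries of IHIN, ORNY and GRMI were not below all random sets for either set. Splits per site were not run without the 3 libraries. At VROH the real split was also the only one as large (9, highest other 8), but the count was 0 without VROH 2, a library of 8840 counts, so nothing is concluded for the site. At SRMI 3 splits were as large (79 genes, highest other 100), so chance is not excluded. At MIWI and MROH the real count was 0, so all 21 splits were as large by construction (highest other 0) and the comparison tests nothing. Over 100 splits of the site libraries, with the controls kept in place, 1, the real one, was as large between sites (2073 genes, highest other 175). That is the smallest share 100 splits can give, so chance is excluded only at that level. Dishes handled in separate batches cannot be told apart from sites here either. Over 100 splits of all libraries, 3 were as large for lists per site (32, highest other 49), a share under 0.05. Since a split gave more, and 21 of the 32 pairs were lost with an estimated correlation, this excludes chance for no single pair. For lists at the mean of sites 19 were as large (3, highest other 7), and for the mean of sites without the 3 libraries 5 were (12 genes, highest other 995), so chance is not excluded; splits with many genes point to a structure of the samples that was not identified.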

How the results depend on the processing

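RLE size factors, leaving out VROH 2, and leaving out VROH 2, CRMI 1 and SRMI 3 together were chosen after seeing the data; the other alternatives were planned. MT1M and MT1G at the mean of sites kept their direction and their side of the threshold under all alternatives run, with MT1M between 0.91 and 1.06 and MT1G between 0.77 and 0.87 without single controls. Of 145 named gene results past the threshold, 40 stayed past it under every alternative; of the 135 with leave-one-out runs, 36 stayed past it in each. A single result turned direction: PCK2 at SRMI ranged from -0.11 without SRMI 3 to 1.78 without SRMI 1, and was at -0.10 without the 3 libraries. Leaving out the filter on low counts ended 55 of the 145, the replicate block 83 and RLE 3. The fit without the 3 libraries ended 13 of 144 compared, PCK2 at SRMI among them, and did not test CHRFAM7A at LRMN. The fits with a site and controls alone ended 20 of 123 compared, and DESeq2 3 of 136. The log2(value + 5), variance moderation and TMM-factor alternatives were not run, since they apply to values that are not counts. Dishes with the same number were not paired: the mean correlation of residuals was 0.0187 over 465 same-number pairs and 0.00162 over 1631 other pairs. The block takes degrees of freedom and leaves out GRMI 1 and MIWI, whose numbers could not be matched. Only controls have the numbers 5 to 8. With the block CTRL 5 to CTRL 8 each had a term of their own and added nothing to the comparisons with the controls. In the simulated data 1.5-fold changes of more abundant features at LRMN were recovered in 37.3% of cases.

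Counts of called genes moved by over 1.5 times as follows; the causes were not tested, except that leaving out the filter tests more features. With DESeq2 the count was 22 at BRWI, 240 at CROH, 18 at FRWI, 6 at GRMI, 24 at GRNY, 4 at IHIN, 43 at JRMI, 82 at MAWI, 2 at MIWI, 2 at MROH, 92 at ORNY, 93 at RRMI, 157 at SRMI and 48 at VROH. Without the filter it was 6 at BRWI, 95 at CRMI, 73 at CROH, 1 at FRWI, 1 at GRNY, 0 at IHIN, 193 at LRMN, 13 at MAWI, 3 at ORNY, 24 at SRMI, 44 at VROH and 2 at the mean of sites, with 1 list there. With the replicate block it was 4 at BRWI, 41 at CRMI, 15 at CROH, 1 at FRWI, 1 at GRMI, 2 at GRNY, 0 at IHIN, 2 at JRMI, 108 at LRMN, 16 at MAWI, 22 at RRMI, 24 at SRMI, 5 at VROH and 2 at the mean of sites, with 1 list there. With RLE it was 6 at GRNY, 18 at JRMI and 134 at SRMI. With the site and controls alone it was 72 at BRWI, 997 at CROH, 274 at FRWI, 57 at GRMI, 110 at GRNY, 326 at IHIN, 139 at JRMI, 1068 at LRMN, 333 at MAWI, 1 at MIWI, 2 at MROH, 243 at ORNY, 311 at RRMI, 2 at SRMI and 1 at VROH. Without the 3 libraries it was 79 at BRWI, 554 at CRMI, 709 at CROH, 151 at FRWI, 38 at GRMI, 634 at GRNY, 38 at IHIN, 201 at JRMI, 1213 at LRMN, 326 at MAWI, 1 at MIWI, 6 at MROH, 283 at ORNY, 198 at RRMI, 12 at the mean of sites and 3446 between sites. Without JRMI, LRMN or RRMI the mean of sites gave 2, and without VROH 8. With an estimated correlation 1 list passed at the mean of sites and 11 pairs of list and site.

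Without single libraries the counts ranged from 4 to 33 at BRWI, 148 to 508 at CRMI, 42 to 289 at CROH, 1 to 23 at FRWI, 1 to 8 at GRMI, 0 to 37 at GRNY, 0 to 7 at IHIN, 0 to 76 at JRMI, 127 to 600 at LRMN, 7 to 108 at MAWI, 0 to 1 at MIWI, 0 to 1 at MROH, 0 to 110 at ORNY, 34 to 121 at RRMI, 5 to 220 at SRMI, 0 to 24 at VROH and 2 to 7 at the mean of sites. The highest value was without VROH 2 at every site other than VROH. Lists ranged from 1 to 4 at the mean of sites and from 30 to 41 over sites, and the count between sites was 2624 without VROH 2.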

Other observations

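The values in this part were chosen after they were seen. Glutamine synthetase GLUL and the serine synthesis enzyme PSAT1 took opposite signs against the controls at 16 of 16 sites in the fit without VROH 2, CRMI 1 and SRMI 3. The sites share the controls, and the share of other gene pairs that do the same was not computed. In that fit GLUL was at 0.69 (log2) and PSAT1 at -1.22 at LRMN, 0.63 and -0.67 at CROH, and -0.61 and 0.44 at MAWI. PSAT1 was at -0.06 at RRMI and 0.17 at GRMI, with libraries on both sides of the control mean at each, so the signs there carry little. PSAT1 was among the probes low in CRMI 1, a set also low in GRNY 2 (-1.71), JRMI 2 (-1.56), GRNY 3 (-1.16) and LRMN 4 (-1.13), libraries of sites where PSAT1 was below the controls. Both differed between sites in that fit, with F = 28.9 for GLUL and F = 18.8 for PSAT1, and with all libraries, with F = 12.8 and 6.51.

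CCN1 is a YAP target like CCN2; the difference between the 2 genes was not tested. As means of library log2 differences without the 3 libraries, CCN2 was at 1.18 at LRMN, 0.73 at GRNY, 0.56 at JRMI, 0.55 at FRWI, 0.49 at BRWI, 0.43 at CROH and 0.37 at VROH, and CCN1 there at -0.23, -0.01, -0.01, -0.02, -0.16, 0.16 and 0.01, within the range of the control libraries (-0.52 to 0.61). The control libraries of CCN2 ranged from -0.26 to 0.65. Among these sites, CCN2 exceeded that range at LRMN and GRNY alone. CCN1 was at -1.63 at GRMI (libraries from -3.26 to -0.36) and at -1.40 at MAWI.

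MRPS6, a mitochondrial ribosomal protein gene (chromosome 21, 34073224 to 34143034, plus strand), overlaps SLC5A3 (34073570 to 34106262, plus strand), the myo-inositol transporter gene of the osmotic stress list, which was not analysed here. MRPS6 was above the controls at 16 of 16 sites, from 0.14 at MAWI to 1.25 at RRMI, without the 3 libraries (mean of sites 0.47 ± 0.07, adjusted p = 0.000103); with all libraries it did not pass (0.46 ± 0.13, adjusted p = 0.427). It was above the odd-numbered and the even-numbered controls at 16 and 16 sites, and above the highest control library at 10. The gene was chosen after its values against these controls were seen, so this is no independent check. With shared controls, 3.37% of features in simulated unchanged groups had 16 of 16 sites on 1 side, against 0.345% observed with all libraries.

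Without the 3 libraries the mean of sites also called ANKRD1 (-0.55), FAM229B (-0.62), ARMH1 (-0.87), the antimicrobial peptide LEAP2 (-0.24), the chemokine CCL20 (0.28), CYP3A7 (0.40) and the mitochondrial NAD kinase NADK2 (0.26), beside MT1M, MT1G, MT2A, NRN1 and MRPS6.

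Over group means without the 3 libraries, a first component held 67.8% of the variance, with the controls at 0. It set CRMI (13.6), MAWI (12.2), IHIN (11.9), GRMI (10.2), SRMI (10.1), ORNY (9.77), MIWI (8.71) and MROH (8.60) against GRNY (-17.7), LRMN (-17.1), CROH (-12.6), JRMI (-11.8), FRWI (-11.3) and VROH (-8.80), with RRMI at -3.92 and BRWI at 0.02. Leaving aside VROH 2, CRMI 1 and SRMI 3, the libraries with the lowest scores of the probe sets low in CRMI 1 or SRMI 3 belong to sites on the negative side: GRNY 2 (-1.71), JRMI 2 (-1.56), GRNY 3 (-1.16), LRMN 4 (-1.13) and FRWI 1 (-0.84) for the first set, and GRNY 4 (-1.55), LRMN 2 (-1.33) and CROH 3 (-1.07) for the second; CTRL 1 follows at -0.61 on the first. CRMI 1 scores -1.09 on the second set, and CRMI lies on the positive side. Whether a feature of the assay or the water sets these sites apart was not tested.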
